A study of Sinorhizobium meliloti 1021 with 6 samples.

How the data were processed

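RNA sequencing values of 6 libraries were used, 1 for each combination of treatment (water, NCR247 or NCR335 at 10 mg/L) and time (10 or 30 min). Per the labels' protocols, cultures in early logarithmic phase were treated, RNA was purified with a RiboPure kit and treated with RQ1 DNase, RNA of 3 biological replicates per condition was pooled, ribosomal RNA was removed with a Ribo-Zero kit, and libraries were sequenced on a SOLiD4 instrument. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here.

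The authors deposited 1 table of RPKM values (reads per kilobase of gene, scaled to library size), per the file headers, with a locus tag, a symbol for 1799 of the 6218 genes and a product description. The peptide columns carry the names of their samples. The control columns are headed K with the time, and were matched to the untreated samples because no other samples remained at those times. All 6 value columns were used. Genes without a symbol are named by locus tag. No genome coordinates were used, and the gene table supplied for another Ensifer species was not used here. The table holds no transfer RNA or ribosomal RNA rows.

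Whole reads were recovered from the RPKM values, since a gene's values are whole multiples of the value of 1 read. The step was set from 9 rows of an insertion-sequence family of 1 length, and for all 6218 genes a coding length in codons was found that turned the 6 values into whole numbers within a tolerance of 1e-05. The library totals that this gave were whole numbers and the reads summed over genes came to 100.03% to 100.2% of them. The recovered lengths were 90 codons for rpsO and 1381 for rpoB. The median gene had 415, 479 and 325 reads in the control, NCR247 and NCR335 libraries at 10 min and 396, 257 and 265 at 30 min. These reads were used for depth and for counting intervals only. Intervals of a fold are exact conditional (Clopper-Pearson) 95% intervals, which cover counting error and neither culture nor library variation.

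RPKM values were divided by a median-of-ratios factor per library, computed over 6084 genes at or above 10 RPKM in all 6 libraries. The factors were 0.875 and 0.876 for the control and NCR247 at 10 min, 1.03 for NCR335 at 10 min, and 0.984, 1.07 and 1.18 for control, NCR247 and NCR335 at 30 min. Log2 ratios are on the log2(scaled RPKM + 1) scale, which understates the change of low genes, and folds are ratios of scaled RPKM. A gene entered a comparison with 10 scaled RPKM or more in at least 1 of the 2 libraries. With 1 library per condition no test was run, and a gene was counted when it differed by at least 2-fold.

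Before the data were examined, 41 gene lists were fixed from symbols and product words; 2 of them matched no row and 38 had at least 3 measured members. A list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a percentile that describes these libraries. Members of an operon are not independent, so more lists than the nominal share lie outside the band from 2.5 to 97.5. The interval of a list median is a 95% order-statistic interval over its members. Similarity between comparisons was set beside 100 simulations of unchanged libraries against the shared control, with gene spread taken from the 2 controls.

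The rule for named genes was also fixed before: the 8 highest and 8 lowest genes of each peptide-control comparison with 1 sign at both times, up to 4 members of each list with the largest absolute mean log2 ratio, the 6 highest and 6 lowest between the peptides, fixed regulators, and the highest gene of each library. Genes chosen after their values were seen were zur, znuB, znuC, hmuV, kdpA, exbB, exbD, SMc00784, SMc01106, SMc00563, SM_b21294, SM_b21295, hspC2 and degP4. Of the fixed regulators, gcrA, visN and rem have no row under those symbols, and groEL stands for 5 unnumbered copies. The rule also named dnaK, groEL, rpoH2, rpoE2, ccrM, ftsZ2, exoR, chvI and flaA, whose values are not printed below. For ctrA only the values between the peptides are printed. The single genes printed are therefore a selection, also among heat-shock genes.

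The procedure was tested on simulated data. For a simulation of NCR247 against control at 10 min over 6218 genes, 98.5% of genes had every read recovered and 1.51% were off by a common factor. A row of 1 read, on which the recovery relies, was placed in each simulated library. All 50 genes set 3-fold higher passed the size rule, and 0 of 5938 unchanged genes did. Apart from the set genes, simulated libraries differed by counting error alone, so the 0 is no false-positive rate for these data. Between the 2 real untreated libraries 58 genes passed the rule. For a simulation of NCR335 against control at 10 min, 3.50% of 200 unchanged lists of randomly drawn genes fell outside the band. Alternatives were values as deposited, scaling from chromosomal genes, pseudocounts of 0.1 and 5, no floor, a floor of 50, the mean of both controls, a 3-fold rule, means over list members, other control pairings and, added after seeing the data, a counting interval that leaves out 1 and the removal of genes high in a single library. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.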

Results

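Messenger RNA levels were measured by RNA sequencing in Sinorhizobium meliloti, a soil bacterium that fixes nitrogen inside the root nodules of legumes. Exponentially growing cultures received sterile water, NCR247 or NCR335 and were sampled after 10 or 30 min. NCR peptides are cysteine-rich peptides that legume nodule cells make and deliver to the bacteria, and both were used here as synthetic peptides at the matched dose of 10 mg/L. RNA of 3 cultures was pooled for each condition, so there were 6 libraries, 1 per condition, and pooling hides the spread between cultures. No difference below has a replicate check and no p-value is given. Values describe these libraries, by a rule of size (2-fold) and with intervals that cover counting error only. Because of the scaling, higher and lower are relative to the other genes of a library. A change in the total amount of messenger RNA cannot be seen in such values. A gene called higher may thus have fallen less than the others.

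The table listed 6218 genes, of which 3359 lie on the chromosome, 1290 on the megaplasmid pSymA and 1569 on the megaplasmid pSymB. The read totals by which the RPKM values were scaled, recovered from the RPKM steps, were 7363588 in the 10 min control, 8602654 with NCR247 at 10 min, 4843112 with NCR335 at 10 min, 6295788 in the 30 min control, 3700607 with NCR247 at 30 min and 3446577 with NCR335 at 30 min. The median gene had 257 to 479 reads. The gene with the highest level was SMc02396, an outer membrane protein, in the 10 min control, and SMc02051, a hypothetical protein, in the other 5 libraries.

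The first comparison asked how NCR247 altered transcript levels within 10 min. Zinc uptake genes were higher: znuA (SMc04245), the zinc-binding component of a high-affinity zinc importer, was 18.4-fold higher than in the control (95% counting interval 16.6 to 20.5), at 1039 against 56.4 scaled RPKM. The adjacent znuC, znuB and zur, the last encoding the zinc uptake regulator and all chosen after their values were seen, were 4.92-fold, 4.47-fold and 6.03-fold higher. SMc04128, a heavy metal transporting ATPase, was 9.21-fold lower (8.66 to 9.80), and SMc04167, a histidine-rich transporter, was 3.89-fold lower. Hemin uptake genes were higher too, with hmuT at 5.58-fold (5.06 to 6.18), hmuS at 5.03-fold, hmuU at 3.41-fold and hmuV at 2.46-fold. The 55 ribosomal protein genes had a median log2 ratio of -1.40, and 41 of them were at least 2-fold lower.

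Of the 27 measured iron uptake and regulation genes, 9 were at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.32, percentile 100 among random lists matched on expression). Of these 9, rhbB of the rhizobactin siderophore cluster was high in that single library and its neighbours were not. The exbB and exbD genes, chosen after their values were seen, whose products energise outer membrane transport, were 3.02-fold and 2.81-fold higher, as was the iron-binding protein SMc00784 at 3.04-fold, while rirA, the iron-responsive regulator, had a log2 ratio of 0.49. Among cyclic glucan genes, ndvA, the cyclic glucan exporter, was 3.07-fold higher, and the regulator feuP 2.44-fold. The gene bacA, encoding a transporter that rhizobia need to survive inside nodule cells, was 2.43-fold higher. With NCR335 the bacA log2 ratio was 0.30 at 10 min and -0.19 at 30 min (0.07 as deposited), short of 2-fold. The potassium-transporting ATPase genes kdpA, kdpB and kdpC had log2 ratios of 1.31, 1.35 and 1.30. On the lower side, 5 of 10 ATP synthase genes were at least 2-fold lower (median log2 ratio -1.01), with atpB and atpE both at -1.48. Median log2 ratios were -0.68 for 15 translation factors, -0.49 for 20 aminoacyl-tRNA synthetases and -0.54 for 26 purine and pyrimidine synthesis genes, all at percentile 0. On pSymB, pdh (SM_b20020), annotated as a pyruvate dehydrogenase component, was 6.20-fold lower, and sucB next to it 2.85-fold lower. The pSymA genes fixK (SMa1225 and SMa0762), transcription regulators of the microaerobic response, were 5.18-fold and 5.11-fold lower, but near-identical copies can share reads, which leaves the split between them uncertain.

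In all, 160 genes were at least 2-fold higher and 116 at least 2-fold lower of 6145 compared. Of the 38 gene lists with a percentile, 18 lay outside the central 95% band of random lists, where 1.9 would by chance if genes were independent, and 9 did so between the 2 untreated libraries.

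The second comparison asked the same of NCR335 at 10 min. All 55 ribosomal protein genes were at least 2-fold lower, with a median log2 ratio of -2.37 (order-statistic interval -2.55 to -2.27), and rpsJ was 7.53-fold lower (6.87 to 8.27). All 10 ATP synthase genes were at least 2-fold lower as well (median -1.69), as were 12 of 15 translation factors, among them fusA1, elongation factor G, at 6.04-fold. The zinc genes were higher as with NCR247, znuA by 12.5-fold (11.2 to 13.9) and zur by 4.46-fold. Of 33 chaperone and heat-shock protease genes, 4 were at least 2-fold higher, 2 at least 2-fold lower and 27 within 2-fold (median log2 ratio 0.49). Among the higher ones, clpB was 4.13-fold (4.01 to 4.26) and ibpA 3.30-fold higher, while hspC2 and degP4, chosen after their values were seen, had log2 ratios of -1.85 and -1.84. The Hsp20 genes SM_b21294 and SM_b21295, also chosen after their values were seen, were 3.77-fold and 3.59-fold higher.

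Of the 9 genes of RNA polymerase and transcription elongation, 8 were at least 2-fold lower (median log2 ratio -1.59), with rpoA at 6.33-fold and rpoB at 4.08-fold. Purine and pyrimidine synthesis genes had a median of -0.83 with 11 of 26 at least 2-fold lower, fatty acid synthesis genes -0.72 with 8 of 21, and lipopolysaccharide, lipid A and capsule genes -0.62 (-0.39 as deposited) with 6 of 28. In the nitrogen fixation and microaerobic list, 16 of 41 genes were at least 2-fold lower and 1 higher (median -0.45, and -0.22 as deposited). The largest ratios there belonged to fixK, with SMa0762 at 13.8-fold (11.9 to 16.2) and SMa1225 at 8.74-fold lower. That list also differed between the untreated libraries, where 12 of its 41 genes were at least 2-fold lower at 30 than at 10 min. The pseudoazurin gene azu1, which carries electrons in denitrification, was 8.73-fold lower, and 3.88-fold lower in the untreated culture at 30 min than at 10 min. Among higher genes, SMc00562, a transcription regulator, and its neighbour SMc00563, a transporter chosen after its values were seen, were 9.05-fold and 5.54-fold higher, and the multidrug efflux genes SMc03167 and SMc03168 4.75-fold and 4.92-fold. The ammonium genes glnK and amtB were 3.97-fold and 3.59-fold higher, and trxA, thioredoxin, 3.92-fold. The hmu genes had a median log2 ratio of 0.94, and exbB one of 0.32. The iron list had a median of 0.42 (0.64 as deposited, percentile 99.99) with 2 of 27 genes at least 2-fold higher and 2 lower, and at 30 min a median of 0.35 (0.61 as deposited, percentile 99.96) with 2 higher and 1 lower.

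With NCR335 at 10 min, 218 genes were at least 2-fold higher and 425 at least 2-fold lower of 6146. The split depended on scaling: with the values as deposited, whose median log2 ratio was shifted by 0.23, the counts were 383 higher and 278 lower.

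The third comparison asked what remained of the NCR247 difference at 30 min. Zinc genes stood closer to the control than at 10 min, with znuA 4.01-fold (3.58 to 4.50), znuB 2.45-fold, znuC 2.21-fold and zur 2.25-fold higher. The hemin genes hmuS and hmuT were 4.37-fold and 4.19-fold higher, and SMc01747, a hypothetical protein, 5.10-fold. SMc02514, a periplasmic binding protein of an ABC transporter, was 5.44-fold higher (5.28 to 5.61), after 10.8-fold at 10 min. Ribosomal protein genes had a median log2 ratio of -1.44 with 42 of 55 at least 2-fold lower, and rplC was 5.16-fold lower (4.82 to 5.53).

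ATP synthase genes had a median log2 ratio of -1.11, with 7 of 10 at least 2-fold lower. RNA polymerase genes had a median of -0.81 and translation factors one of -0.80. Chaperone and protease genes had a median of 0.45 with 4 of 33 at least 2-fold higher, among them ibpA at 3.18-fold and clpB at 2.70-fold, while the same list had a median of -0.27 (-0.11 as deposited) in the untreated culture from 10 to 30 min. The gene of the heat-shock sigma factor RpoH1 was 2.06-fold higher. The iron list had 8 of 27 genes at least 2-fold higher and 1 lower. The kdp genes, at 2.48-fold to 2.58-fold higher at 10 min, had log2 ratios of -0.18, -0.05 and -0.17 for kdpA, kdpB and kdpC. The bacA log2 ratio was 0.55, and pdh was 5.61-fold lower. SMc04128 was 4.81-fold lower.

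In total 112 genes were at least 2-fold higher and 126 at least 2-fold lower of 6151. As deposited, with a shift of 0.11 in the median log2 ratio, the counts were 163 higher and 100 lower.

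The fourth comparison covered NCR335 at 30 min. All 55 ribosomal protein genes were again at least 2-fold lower, with a median log2 ratio of -2.38 (-2.45 to -2.26), and rplC was 7.55-fold lower (6.97 to 8.20). ATP synthase genes had a median of -1.64 and RNA polymerase genes one of -1.65, with rpoA 5.55-fold lower. Single heat-shock genes were higher, ibpA by 4.55-fold (4.46 to 4.63), clpB by 4.25-fold, SM_b21294 by 5.30-fold, SM_b21295 by 4.39-fold and the small heat shock protein gene SMc01106 by 3.36-fold. The gene znuA was 4.69-fold higher (4.20 to 5.25) and SMc02514 5.80-fold higher.

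The chaperone and protease list had 8 of 33 genes at least 2-fold higher and 2 lower (median 0.49, and 0.76 as deposited). Aminoacyl-tRNA synthetases had a median of -0.85, with aspS at -1.78 and tyrS at -1.41. The thioredoxin gene trxA was 3.18-fold higher and msrA1, a methionine sulfoxide reductase, 2.72-fold. In the oxidative stress list 4 of 30 genes were at least 2-fold higher, and katA, catalase, had a log2 ratio of 0.51. SMc00562 was 5.54-fold and exoI, a gene of the succinoglycan cluster, 3.29-fold higher, while mucR, a regulator of exopolysaccharide genes, was 2.73-fold lower. The list of succinoglycan genes and their regulators, which holds exoI and mucR, had a median of -0.18 (0.08 as deposited), so its direction depends on scaling. Of the nitrogen fixation and microaerobic list, 6 of 41 genes were at least 2-fold lower, with fixK at 6.36-fold (SMa1225) and 6.19-fold (SMa0762). The list's median of -0.13 was 0.13 with the values as deposited and 0.00051 with scaling from chromosomal genes, so its direction depends on scaling.

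Here 243 genes were at least 2-fold higher and 348 at least 2-fold lower of 6156. As deposited, with a shift of 0.26, the counts were 475 higher and 209 lower, and with scaling from chromosomal genes 319 and 268.

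**Figure D1:**
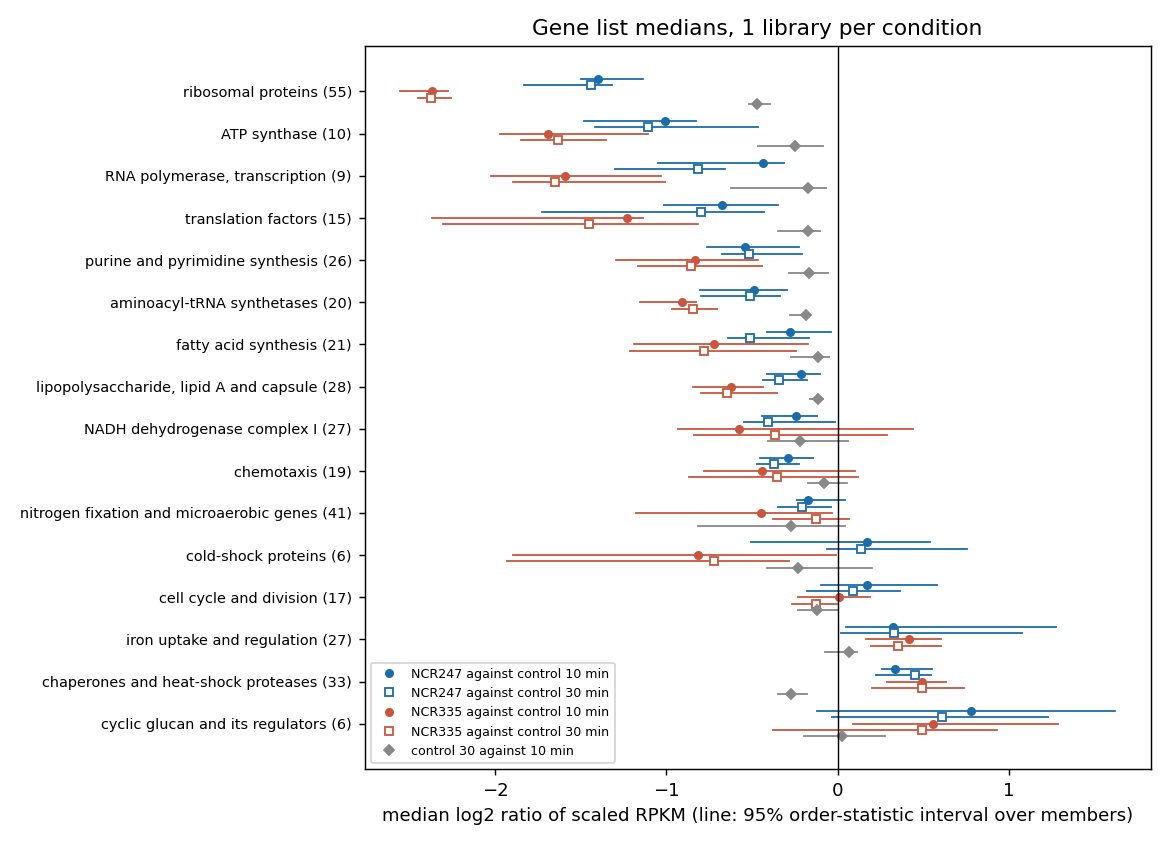
Median log2 ratio of scaled RPKM (x axis) for 16 gene lists (y axis, number of measured genes in brackets) in the 4 peptide-control comparisons and between the untreated libraries. Circles are 10 min, open squares 30 min, diamonds the control at 30 against 10 min, and lines the 95% order-statistic interval over list members. Ribosomal protein medians are -1.40 and -1.44 with NCR247, -2.37 and -2.38 with NCR335, and -0.47 between the controls.

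The peptides were then compared directly at the same time and at a dose matched by mass. Molar doses were not compared, so equal exposure by number of molecules is not implied. At 10 min the ribosomal protein genes were lower with NCR335 than with NCR247 by a median log2 ratio of -1.09, with 33 of 55 at least 2-fold lower, and at 30 min by -0.71 with 16 of 55. As deposited these medians were -0.86 and -0.56, and with chromosomal scaling -0.97 and -0.61. The 10 min median thus fell short of 2-fold under both other scalings, with the same sign. The 6 cold-shock protein genes had medians of -0.97 at 10 min and -1.22 at 30 min for NCR335 against NCR247, at percentiles 3.10 and 0. As deposited these medians were -0.74 and -1.08. Among them, cspA8 was 3.42-fold and 3.65-fold lower with NCR335, and cspA2 3.35-fold and 2.98-fold lower. The chaperone and heat-shock protease list had 2 of 33 genes at least 2-fold higher and 4 lower at 10 min (median 0.07, and 0.30 as deposited, percentile 99.8), and 1 higher and 3 lower at 30 min (median 0.10, and 0.25 as deposited, percentile 99.5). The Hsp20 gene SM_b21295, which is not in that list and was chosen after its values were seen, was 4.07-fold (3.93 to 4.21) higher with NCR335 at 10 min and 3.65-fold at 30 min, while hspC2 had log2 ratios of -1.75 and 0.31. The 4 hmu genes had median log2 ratios of -0.94 at 10 min and -0.89 at 30 min, short of 2-fold, and ranged from -1.41 to -0.55 and from -1.28 to -0.50. The lowest was hmuT, 2.66-fold (2.46 to 2.89) and 2.44-fold lower with NCR335.

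The gene of the replication initiator DnaA was 2.45-fold lower with NCR335 than with NCR247 at 10 min and 2.10-fold lower at 30 min, and mucR 2.40-fold and 2.84-fold lower. SMc02156, a hypothetical protein, was 4.12-fold and 4.56-fold lower with NCR335. On the higher side SMc00563 was 5.53-fold and 3.26-fold, pdh 3.81-fold and 2.48-fold and exoI 2.86-fold and 3.19-fold higher with NCR335. The gene znuA was 1.48-fold lower with NCR335 (1.42 to 1.54) at 10 min and 1.17-fold higher (1.08 to 1.27) at 30 min. The gene rpoH1 had log2 ratios of -0.05 and -0.14, smaller than the scaling shifts of 0.22 and 0.15 given below, so their direction is not settled. The cell cycle and division list of 17 genes had a median of -0.13 at 10 min, which was 0.10 with the values as deposited, and of -0.27 at 30 min, which was -0.13 as deposited, and the regulator gene ctrA had log2 ratios of -0.65 and -0.27. In total, 167 genes were higher and 253 lower by 2-fold at 10 min, and 126 and 121 at 30 min. As deposited these splits were 309 and 148, and 197 and 76, with shifts of 0.22 and 0.15, and with chromosomal scaling 230 and 189, and 170 and 92.

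The 2 times were compared within each treatment, 1 library against 1, so time cannot be told from variation between libraries. With a peptide, the length of exposure changes along with time. Between the untreated libraries, ribosomal protein genes were lower at 30 min by a median log2 ratio of -0.47 (-0.31 as deposited), with 0 of 55 at least 2-fold lower. Chaperone and protease genes had a median of -0.27 (-0.11 as deposited), with 1 of 33 at least 2-fold lower. Of the nitrogen fixation and microaerobic list, 12 of 41 genes were at least 2-fold lower at 30 min (median -0.27, and -0.11 as deposited), and of the denitrification list 5 of 23 (median -0.25, and -0.08 as deposited). Among these genes fixH had a log2 ratio of -1.99, azu1 of -1.95, nosR of -1.51 and hemN of -1.25. The control comparison held 15 genes at least 2-fold higher and 43 at least 2-fold lower at 30 min. NCR247 at 30 against 10 min gave 56 and 96, and NCR335 gave 69 and 46. As deposited, with shifts of 0.17, 0.28 and 0.20 and with the floor applied to the deposited values, the splits were 29 and 31, 148 and 40, and 109 and 23. Over the genes that pass the floor after scaling, the NCR247 split as deposited was 147 and 40. With chromosomal scaling it was 75 and 72.

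Similarity of the 2 peptides was described across genes, which are not independent replicates. At 10 min the log2 ratios of NCR247 and NCR335 correlated with a Pearson r of 0.58 (Spearman rho 0.50), and 67 genes were at least 2-fold higher in both and 87 lower in both, where independent lists would share 5.67 and 8.09. At 30 min r was 0.66 (rho 0.61), with 50 and 97 shared genes against 4.42 and 7.12. Both peptides share a control library. Simulated unchanged libraries gave an r of 0.50 at either time, which follows from setting 2 libraries of equal spread against 1 control. They shared on average 0.38 higher and 0.39 lower genes at 10 min, and 0.45 and 0.39 at 30 min. The simulated spread was normal within each expression bin, while 58 genes were at least 2-fold apart between the real untreated libraries. The simulated overlaps may therefore be too low. The covariance was 0.188 at 10 min and 0.191 at 30 min, against 0.0387 and 0.0389 in the simulations. Part of the overlap may come from the shared control, so pairs with no library in common were set beside it: NCR247 at 10 min and NCR335 at 30 min gave an r of 0.40 with 40 and 80 shared genes, and NCR247 at 30 min and NCR335 at 10 min gave 0.56 with 48 and 95. With 1 peptide set against the control of the other time, r at 10 min was 0.53 (NCR335 moved) or 0.31 (NCR247 moved), and at 30 min 0.56 (NCR335 moved) or 0.65 (NCR247 moved). Between times, each with its own control, NCR247 gave an r of 0.60 with 69 genes higher and 69 lower at both times, and NCR335 an r of 0.76 with 107 and 281.

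**Figure D2:**
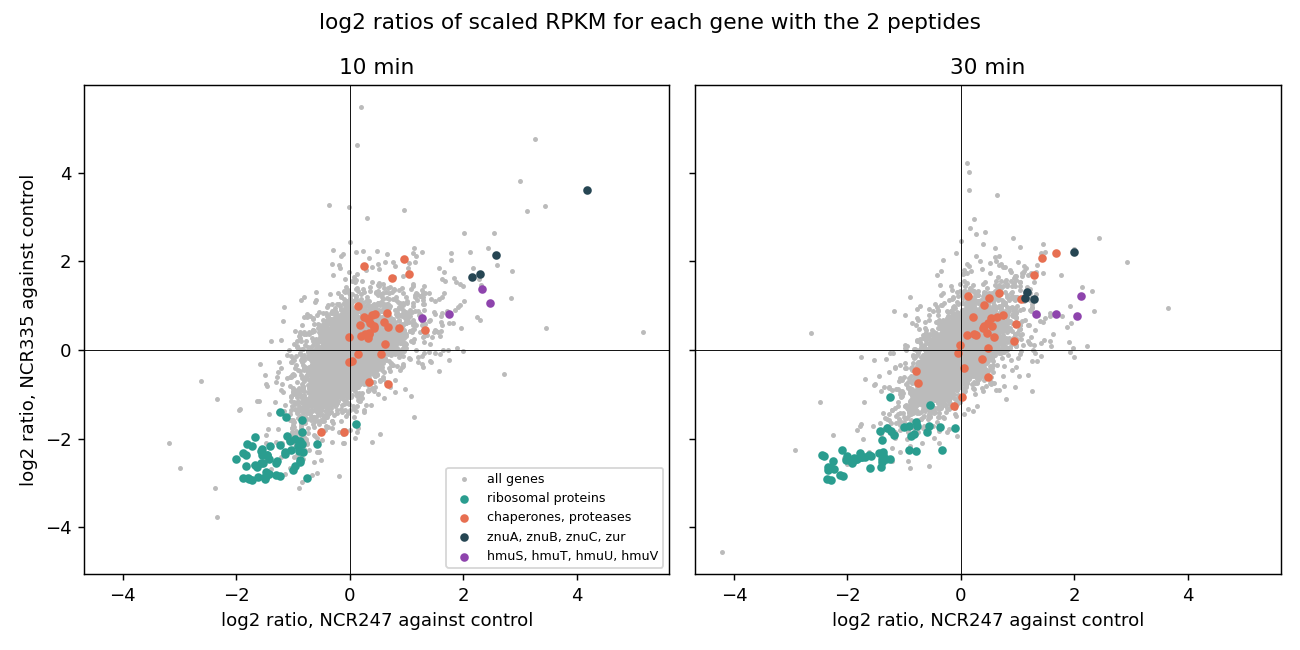
log2 ratio against the control of the same time for NCR247 (x axis) and NCR335 (y axis), 1 point per gene at or above 10 scaled RPKM in at least 1 library, at 10 min (left) and 30 min (right). Coloured points are ribosomal protein genes, which lie below 0 for NCR335 in both panels, chaperone and protease genes, the 4 zinc uptake genes and the 4 hemin uptake genes, for which the NCR247 ratio is the higher one.

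Some genes were high in a single library. There were 20 genes with at least 50 scaled RPKM in 1 library and at least 4-fold more than in every other library, chosen after the values were seen. The largest was SMc00300, a pyridine nucleotide transhydrogenase, with 12290 scaled RPKM with NCR335 at 10 min and at most 366 elsewhere. Others were SM_b20296, a permease, rhbB and engB with NCR247 at 10 min, nuoF2 with NCR335 at 10 min, SMc01702, SMc04241 and fixB with NCR335 at 30 min, and tpiA (SMc01023), triosephosphate isomerase, in the 30 min control at 3432 against at most 317. The log2 ratios of tpiA at 30 min, -4.21 with NCR247 and -4.55 with NCR335, therefore rest on that control library. The genes SM_b20588 and SM_b21604, up to 27.5-fold and 14.2-fold higher with peptide, and SMc03799, up to 8.99-fold higher, were high in several peptide libraries, while the means over their adjacent genes with NCR335 at 10 min were log2 ratios of 0.06, -0.02 and 0.54.

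**Figure D3:**
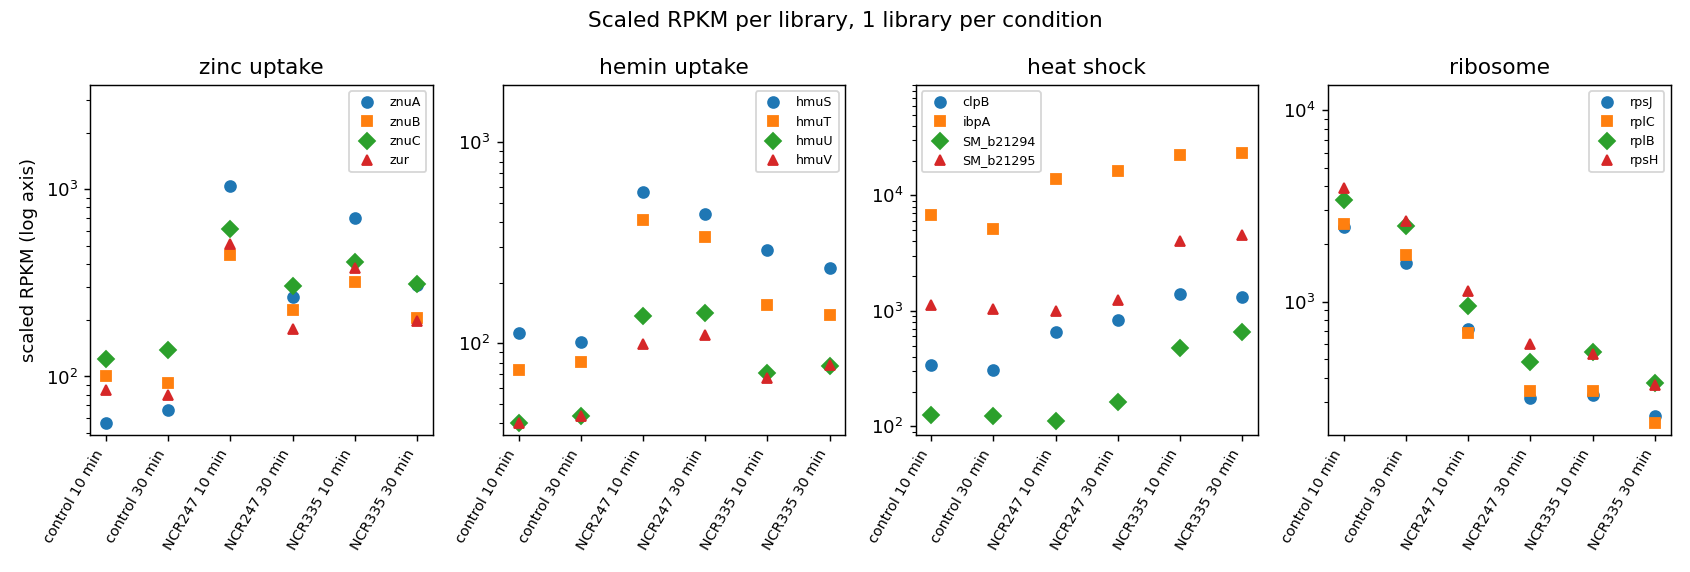
Scaled RPKM (y axis, log scale) of 4 zinc uptake, 4 hemin uptake, 4 heat-shock and 4 ribosomal protein genes in each of the 6 libraries (x axis), 1 point per gene and library. The znuA level is 56.4 and 65.8 in the controls and 1039 with NCR247 at 10 min.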

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

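The percentile among random lists of like expression was planned, and its use against an explanation and the other tests of this part were chosen only after the results were seen. The gene phnM (SM_b21171) differed in direction between times and between peptides. With NCR247 its log2 ratio was 1.14 at 10 min and -1.07 at 30 min, and at 10 min it was 1.14 with NCR247 and -1.50 with NCR335. The mean log2 ratio over its 2 adjacent genes was -0.57 and -0.09 with NCR247 at 10 and 30 min. With NCR335 at 10 min that mean was -0.56. The adjacent genes thus did not share the higher phnM level with NCR247 at 10 min. Each value is 1 library against 1 control, and the difference itself was not tested.

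Ribosomal protein genes were lower with both peptides at both times. The values argue against a drop shared evenly by transcripts of like abundance. The highest percentile of the list median among random lists of like expression was 0 in the 4 peptide-control comparisons. List medians were -1.40, -2.37, -1.44 and -2.38, and the band of random lists reached down to -0.45. The lists were matched in 20 bins of mean level over all 6 libraries. A drop confined to the most abundant genes of a bin is therefore not excluded. A bias of short genes is argued against, since the highest percentile among random lists of like length was also 0. The expression-matched percentile was 0 between the untreated libraries too, at a list median of -0.47. The percentile alone thus does not separate peptide from time or from variation between libraries. A response of growth to the peptides was not tested and stays open as a hypothesis.

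The genes high in a single library form another pattern. Their 95% counting intervals of the fold over the next library had lower ends of 3.55 or more, which follows in part from the 4-fold rule that chose them and is no test of counting error. Of 40 adjacent genes, 2.5% were at least 2-fold higher in that library, against 33.2% of 319 neighbours of genes that were 2-fold higher with 1 peptide at both times. The 2 shares use unlike measures: the 40 were set against the median of the other libraries, the 319 by their mean peptide-control log2 ratio. The 319 also include neighbours that met the 2-fold rule themselves, which raises their share. The shares were chosen after the median log2 ratio of the adjacent genes, 0.13 against 0.46, did not separate the cases. A response of a whole transcription unit is therefore left open. Of the 20 genes, 3 peaked in an untreated library. For the 17 that peaked in a peptide library, an amplification or counting fault at 1 locus and a true change of a single gene cannot be told apart, because positions of reads within genes were not analysed here.

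Hemin uptake genes were higher with NCR247. The log2 ratios of the 4 hmu genes were 1.28 or more in both NCR247 libraries, which describes the pattern and tests no explanation. The 7 rhizobactin siderophore genes had a median log2 ratio of at most 0.21 with NCR247 at 10 and 30 min. This argues against iron limitation that had reached these genes by 30 min. No size of rise was fixed beforehand, and a later rise is not excluded. In the wider iron list, 9 of 27 genes were at least 2-fold higher with NCR247 at 10 min and 0 lower. At 30 min 8 were higher and 1 lower. A narrower change in iron or heme sensing remains possible and was not tested.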

How the results depend on the processing

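The labels give no shared replicate numbers, so no fit with the replicate as a block could be made. Peptide and control were compared within each time. A fit of treatment blocked on time was possible and was not run, since it would take any change of the peptide difference between times as error. Totals of higher and lower genes together stayed within 1.5 times of the reported ones under the other scalings, pseudocounts, floors and the mean of both controls, and under the 2 settings chosen after seeing the data (a counting interval that leaves out 1, and leaving out genes high in a single library). The division into higher and lower moved more: as deposited, higher genes went from 218 to 383 and from 243 to 475 with NCR335 at 10 and 30 min, and with NCR247 over time from 56 to 148, while lower genes there went from 96 to 40. A 3-fold rule, which by construction counts fewer genes, gave 84 (NCR247 at 10 min), 221 (NCR335 at 10 min), 66 (NCR247 at 30 min), 179 (NCR335 at 30 min), 90 and 54 (between peptides at 10 and 30 min), 13 (controls), 34 (NCR247 over time) and 42 (NCR335 over time). The ribosomal protein median with NCR335 at 10 min was -2.14 as deposited, -2.27 with chromosomal scaling and -2.19 with both controls; at 30 min it was -2.12, -2.25 and -2.64, and the mean over members was -2.26. The nitrogen fixation and microaerobic median with NCR335 at 30 min changed sign, to 0.13 as deposited and 0.00051 with chromosomal scaling, and the nodulation median there, -0.05, to 0.209 and 0.0783. The transposase median with NCR247 at 30 min, -0.05, became 0.0696 as deposited, 0.0199 with no floor and 0.0166 with both controls, and with NCR335 at 30 min 0.0041 became -0.0521 with a floor of 50. The causes were not tested. The correlation of the peptides at 10 min was 0.31 with NCR247 and 0.53 with NCR335 against the 30 min control and 0.40 with no shared library, and at 30 min 0.56 with NCR335 and 0.65 with NCR247 against the 10 min control and 0.56 with no shared library, settings that remove the shared control. Of 1216 recomputed values of 38 lists 1148 kept their sign, and apart from the 8 given above the others belonged to lists inside the band of random lists. Named genes, apart from those named only as list members, were recomputed only in the peptide-control comparison with their largest absolute log2 ratio. Of these 495 recomputed values, 0 that were at least 2-fold apart changed sign. A pseudocount cannot turn a sign and the shifts between scalings were well under 2-fold. The count was thus nearly fixed in advance and is no check of smaller ratios. The table holds protein-coding rows only, so a protein-coding filter gave no other value. Depth limits low genes most in the 30 min peptide libraries, where the median gene had 257 and 265 reads.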

Other observations

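No hypothesis was tested in this part. Some lists lay inside the band of random lists of like expression in the 4 peptide-control comparisons. The 17 cell cycle and division genes had percentiles of 77.7, 79.2, 87.6 and 75.3 in the 4 peptide-control comparisons, and ftsZ1 log2 ratios of 0.01 and 0.02 at 10 min with NCR247 and NCR335. The 18 DNA repair and SOS genes had medians of -0.01, -0.21, 0.04 and -0.13, of which both NCR335 values were above 0 as deposited. Among sigma factor genes, rpoH1 had log2 ratios of 1.11 and 1.06 at 10 min and 1.04 and 0.90 at 30 min. Of 25 nodulation genes, 0 were at least 2-fold apart in any of the 4 comparisons, while the list's percentile at 30 min was 0.23 with NCR247 and 1.36 with NCR335, where the median of -0.05 was 0.21 as deposited and 0.08 with chromosomal scaling, so its direction depends on scaling.

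The gene dnaA had a log2 ratio of 0.15 with NCR247 and -1.14 with NCR335 at 10 min, and mucR -0.13 and -1.39. The cytochrome bc1 genes fbcF, fbcB and fbcC had log2 ratios of -2.05, -1.72 and -1.33 with NCR335 at 10 min and -0.78, -0.86 and -0.88 with NCR247. The phosphate transport genes phoT and phoE had -0.94 and -1.26 with NCR335 at 10 min and -0.99 and -0.90 with NCR247. The phosphate regulon list as a whole had medians of 0.07 (0.30 as deposited) with NCR335 and -0.25 with NCR247 at 10 min.

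The zinc genes form a set that was higher with both peptides: znuA, znuB, znuC and zur had median log2 ratios of 2.43 and 1.93 at 10 min and 1.22 and 1.24 at 30 min for NCR247 and NCR335, against 0.03 between the controls. SMc04128, annotated as a heavy metal transporting ATPase, was lower in the same libraries. No measurement of metals was analysed here, and no explanation was tested.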
